A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

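Chromatin immunoprecipitation followed by sequencing measured H3K4me3 and H3K27me3 in whole rice seedlings of 11 days. Per the labels, the 4 libraries were 1 of each mark from Hwayong (HY) and 1 of each mark from the line labelled chd1(chr729), called chd1 here. Each group held 1 library, so the differences had no replicate check, no p-value was computed, and every comparison was between 2 libraries and not between the conditions.

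The deposited alignments were in SOAP format and held 1 line per aligned read of 49 bases, with the number of equally good places, the position, the strand and up to 2 mismatches. The aligner version and the genome build are not given in the sources used here. Positions are therefore those of the deposited files on 12 chromosomes, counted from 1. The deposited peak lists were called with MACS in each library separately and without a control library, per the file headers. The headers gave a p cutoff of 1e-05, a band width of 200 bp, a genome size of 3.72e+08, a model fold of 10 to 32, a range of 5000 bp for the regional background and at most 2 tags at a position. They gave fragment sizes d of 223 bp for HY H3K4me3, 191 bp for chd1 H3K4me3, 202 bp for HY H3K27me3 and 200 bp for chd1 H3K27me3. The tag count of a peak was a raw count of reads, per the file headers. The peak score was the caller's negative log10 of the p-value, multiplied by 10, per the file headers of the HY H3K4me3 list, and the same column had lost its name in the other lists. The fold enrichment was the authors' ratio of reads at a peak to the local background of the same library. Folds were used only within a list, and scores also as 1 minimum for all lists in an alternative.

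Reads with 1 place were kept, and 1 read was kept per position and strand. The numbers of reads before and after that step equalled the total and unique tags in the headers of all 4 peak lists. The 5 prime end of each read was moved 75 bp in the read direction. Overlapping peaks of the HY and chd1 lists of a mark were merged into regions, and reads were counted in each. Reads were scaled to RPM, that is to a common total of kept reads. Ratios were log2 of chd1 over HY RPM, with a pseudocount of 0.5 reads. A region was counted as lower or higher when the higher library held at least 50 reads, the fold was at least 2, and the exact binomial 95% interval of the ratio excluded a fold of 1. Intervals of RPM were exact Poisson intervals, shares had exact Clopper-Pearson intervals, and the interval of a median came from 1000 Poisson redraws of the reads. Reads carried no molecular identifiers, so all intervals cover counting error only. No input or spike-in reads were used here, so a shift shared by all regions was not separated from the yield of the precipitation. Peaks were counted as shared when they overlapped by at least 1 bp.

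The plan, written before the data were examined, was to count genes in windows around transcription starts. No annotation of the build of the files was used here, so regions by position took the place of genes, as the plan allowed, and the fixed lists of gene identifiers and product names were not analysed here. The regions named in the text are those past the rule with at least 100 reads in the higher library, up to 10 with the largest fold each way for each mark. Reads without mismatches spelled 90.3% of the bases up to the last aligned position of each chromosome. Those bases were translated and searched for 32 peptide patterns of gene families, so that loci of a family could be placed by position. The patterns were chosen after the absence of an annotation was known, and they were loosened 1 time, after the numbers of loci had been seen and before any read value of a family was computed. No YABBY locus was found. Places of single genes, that of CHR729 among them, were also guessed from remembered protein sequence, and their reads were seen before these places were left out for want of a source. A pattern finds only part of a family and can match pseudogenes. For H3K4me3 a region belonged to a family when it overlapped the span from 2000 bp upstream to 500 bp downstream of a match, and for H3K27me3 when it lay within 1000 bp. The median of a family with at least 5 regions was placed among 10000 random lists of regions matched on reads in 20 classes, as a description of these libraries. Lists matched also on which libraries had a peak, with reads in 5 classes, were added after the values had been seen.

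Dense H3K27me3 domains, long blocks and an adjustment for GC content were added after the data were examined. Domains were runs of 1-kb bins with at least 4 times the median reads of both libraries together, at least 3 kb long. Blocks were stretches of at least 40 kb in which the ratio departed from its median by at least 0.7 on the log2 scale in windows of 40 kb with at least 300 reads. The evenness of a block was the chi-square of its 10-kb bins of at least 20 reads around 1 ratio per block, over the degrees of freedom. The GC adjustment subtracted the ratio of bins without a peak in the same of 20 GC classes.

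The alternatives settled in the plan covered duplicates, reads of several places, scaling by trimmed means (TMM) or by reads in bins without a peak, equal depth, the read shift, the pseudocount, the fold, the read minimum, the peak score and the overlap. The counting rule was tested on simulated reads with 200 changed regions per comparison. It called 48.5% of the regions changed by a fold of 2 in the H3K4me3 simulation and 100% of those changed by a fold of 3 or 4. The share at a fold of 2 is set by the threshold of 2 and does not measure the depth. The H3K27me3 simulation gave the same shares, and that of the domains gave 45.6% and 100%. Of the unchanged regions it called 7 of 14507 for H3K4me3, 2 of 2666 for H3K27me3 and 0 of 1794 for the domains. The simulated libraries had no shared shift, no trend with GC content and no choice of regions by their peaks. These counts are therefore not false-call rates of the real libraries. Reads redrawn around the median H3K4me3 ratio gave 114.62 lower regions on average. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.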

Results

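H3K4me3, a histone mark found at the start of active genes, and H3K27me3, the mark laid down by Polycomb repressive complex 2, were mapped in 11-day rice seedlings of Hwayong (HY) and of chd1(chr729), a line named for the chromatin remodeller CHR729. The position of CHR729 is not given in the sources used here, so no reads over the targeted gene are reported and the genotype labels were not checked in that way. A place for it was guessed from remembered peptide sequence and the reads there were seen, but that place rests on no source used here and is left out. The HY H3K4me3 library held 7511601 aligned reads, of which 5767068 remained after filtering, and the chd1 H3K4me3 library held 7607274, of which 5287210 remained. The HY H3K27me3 library held 8364967 aligned reads and kept 6304335, and the chd1 H3K27me3 library held 10645949 and kept 7682407. Reads repeated at a position and strand made up 5.90% and 7.44% of the uniquely aligned reads in the HY libraries of H3K4me3 and H3K27me3, and 13.4% and 11.6% in the chd1 libraries. There was 1 library per group, so the values below have no replicate check and their intervals cover counting error only.

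The H3K4me3 comparison asked where this mark differed between chd1 and HY seedlings. H3K4me3 peak regions held fewer reads in the chd1 library across all 12 chromosomes. The median log2 ratio of chd1 to HY over 17575 regions was -0.35 (interval -0.35 to -0.34), and 89.4% of the regions lay below 0. On single chromosomes the median went from -0.37 on chromosome 4 to -0.33 on chromosome 12. Of 15474 regions with enough reads, 169 were at least 2-fold lower in chd1 and 23 were at least 2-fold higher. Scaling by TMM, which sets the typical region to no change, moved the median to 0.00 and left 16 lower and 41 higher, and scaling by reads in bins without a peak moved it to -0.46, with 374 lower and 16 higher. Over 2-kb bins with or without a peak the counts were 147 lower and 138 higher. With duplicates kept they were 298 and 45 in the peak regions, with reads of several places kept 37 were higher, and after the GC adjustment 109 were lower and 19 higher. With a minimum of 20 reads, or none, 250 were lower and 55 higher.

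**Figure D1:**
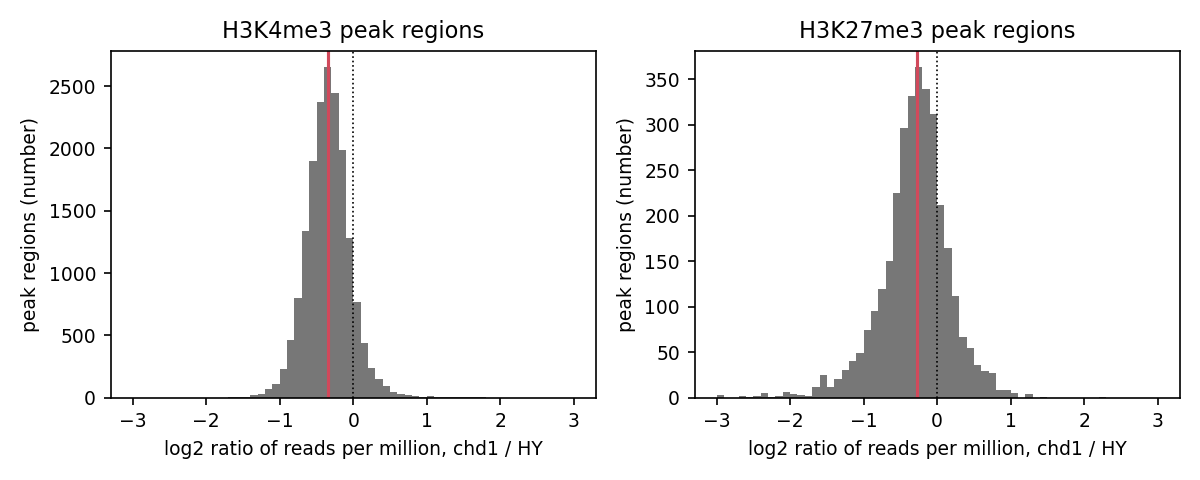
Histograms of the log2 ratio of RPM, chd1 over HY (horizontal axis), with the number of peak regions (vertical axis), for H3K4me3 on the left and H3K27me3 on the right. The red lines mark the medians of -0.35 and -0.27, the dotted lines mark 0, and ratios beyond the axis are drawn in its end bars.

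The list of HY H3K4me3 peaks was longer than that of chd1. HY had 16944 peaks that covered 23.6 Mb with a median width of 1320.5 bp, and chd1 had 13551 peaks that covered 16.2 Mb with a median width of 1128 bp. Own peaks took 28.6% of the HY reads (interval 28.5% to 28.6%) and 18.8% of the chd1 reads (interval 18.8% to 18.8%). Of the HY peaks, 4036 (23.8%, interval 23.2% to 24.5%) had no chd1 peak, while 632 of the chd1 peaks (4.66%, interval 4.31% to 5.03%) had no HY peak. The HY peaks without a chd1 peak had a median fold enrichment of 4.78 in the authors' list, against 5.54 for the shared ones. In the regions with only an HY peak the median log2 ratio was -0.51, in 12907 regions with both it was -0.32, and in regions with only a chd1 peak it was 0.21. These groups were sorted by peaks called from the same reads, which by itself lowers the first ratio and raises the last. It can also lower the median over all regions, in which those with only an HY peak outnumbered those with only a chd1 peak. Among equally many of the best-scored peaks from both lists, 13.3% of the HY peaks had no chd1 peak, and at a score of at least 100 the share was 44.2%.

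Among the H3K4me3 regions with at least 100 reads in the higher library, the lowest ratio lay on chromosome 2 from 13137602 to 13138753. It held 113 reads in HY (19.6 RPM, interval 16.1 to 23.6) and 26 in chd1 (4.92 RPM, interval 3.21 to 7.21), a log2 ratio of -1.97 (interval -2.67 to -1.37). A region on chromosome 11 from 8592190 to 8593805 held 113 and 38 reads, a log2 ratio of -1.43. On chromosome 8 the regions from 6054589 to 6056059 and from 24880416 to 24881836 had ratios of -1.32 and -1.27. The other 6 named lower regions had ratios from -1.16 on chromosome 2 at 34469829 to -1.10 on chromosome 12 at 860843, and they included a region near a NAC locus on chromosome 1 from 34691864 to 34693480 (131 and 55 reads, -1.12, with -0.77 under TMM and -0.91 after the GC adjustment). NAC proteins are plant transcription factors. Of these 10 regions, 2 were still past the rule under TMM and 5 after the adjustment for GC content. Reads redrawn around 1 common ratio gave 114.62 lower regions on average and 142 at most in 100 simulations, against 169 counted, and 0.02 higher regions on average, against 23. These redraws left out the trend of the ratio with GC content and the choice of regions by their peaks.

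The regions with more H3K4me3 in chd1 were few and partly clustered. The region on chromosome 1 from 33548764 to 33550616 held 43 reads in HY and 121 in chd1, a log2 ratio of 1.61 (interval 1.10 to 2.16). Those on chromosome 12 from 20597447 to 20600037 (114 and 244 reads) and on chromosome 9 from 4722487 to 4724413 (70 and 139 reads) had ratios of 1.22 and 1.11. All 3 lay in longer stretches in which H3K4me3 reads were higher in chd1 inside and outside peaks, and 6 of the 23 higher regions did. The last named region, on chromosome 4 from 9188354 to 9189388, held 56 and 108 reads, a ratio of 1.07, and was not past the rule with reads in bins without a peak as the scale (0.96) or after the GC adjustment (0.88).

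The H3K27me3 comparison asked the same of the Polycomb mark. Over 3258 H3K27me3 peak regions the median log2 ratio of chd1 to HY was -0.27 (interval -0.29 to -0.26), and 77.5% of the regions lay below 0. Of 2927 regions with enough reads, 173 were at least 2-fold lower in chd1 and 7 were higher, while over 2-kb bins with or without a peak 450 were lower and 450 higher. Reads redrawn around 1 common ratio gave 5 lower regions on average and 13 at most. The redraws held neither the trend of the ratio with GC content nor the choice of regions by their peaks. The excess of counted regions over them was thus not shown to be local change. TMM moved the median to 0.00 and left 81 lower and 32 higher regions, and the GC adjustment left 69 lower and 6 higher. With duplicates kept 234 were lower and 13 higher.

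HY had 2625 H3K27me3 peaks that covered 4.33 Mb and chd1 had 1780 that covered 3.08 Mb, with median widths of 1543 bp and 1610.5 bp. Own peaks took 4.62% of the HY reads and 2.87% of the chd1 reads. Of the HY peaks, 1479 (56.3%, interval 54.4% to 58.3%) had no chd1 peak, and 635 of the chd1 peaks (35.7%, interval 33.4% to 37.9%) had no HY peak. The median log2 ratio was -0.48 in the regions with only an HY peak, -0.21 in 1144 regions with both and 0.15 in the regions with only a chd1 peak. As for H3K4me3, sorting by these peaks by itself lowers the first ratio and raises the last.

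The H3K27me3 regions named by the rule showed wider differences than those of H3K4me3. On chromosome 5 from 28509854 to 28511802, 210 HY reads (33.3 RPM, interval 29.0 to 38.1) stood against 41 in chd1 (5.34 RPM, interval 3.83 to 7.24), a log2 ratio of -2.63 (interval -3.16 to -2.15). H3K4me3 in the same region had a ratio of 0.15. On the same chromosome the regions from 22945022 to 22946903 (131 and 27 reads) and from 18074963 to 18076780 (150 and 35 reads) had ratios of -2.54 and -2.37, and on chromosome 4 the region from 27230066 to 27231815 (117 and 25 reads) had -2.49. The other 6 named lower regions went from -1.90 on chromosome 1 at 5382718 to -1.55 on chromosome 9 at 7076231. On chromosome 10 from 15822499 to 15825156 both marks were lower in chd1, with ratios of -1.63 for H3K27me3 and -1.04 for H3K4me3 (59 and 26 reads). In the other direction, the region on chromosome 2 from 16250879 to 16253161 held 24 reads in HY and 142 in chd1, a log2 ratio of 2.25 (interval 1.65 to 2.97). Regions on chromosome 6 from 10779354 to 10782140 and from 19331806 to 19333724 had 1.27 and 1.05, and a region on chromosome 10 from 15427393 to 15429681 had 1.22. All 10 lower and all 4 higher named H3K27me3 regions were past the rule under TMM, with reads in bins without a peak as the scale, and after the GC adjustment. The bins used for that adjustment had a ratio of 0.37 in the lowest GC class and -0.53 in the highest, which spanned 60.7% to 100% GC. On chromosome 4 the GC-rich regions at 23634796 and 25161704 went from -1.58 and -1.69 to -1.05 and -1.17, so the first passed narrowly. The scale of bins without a peak moved every H3K27me3 ratio alike and little, the first from -2.63 to -2.64. It could therefore hardly change a call.

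Much of the H3K27me3 signal lay outside the peak lists, in broad domains found from the reads after the data were examined. There were 1994 dense domains with a median width of 5000 bp, together 13.1 Mb, and 88.3% of them held no peak of either library. They took 17.5% of the HY reads and 15.3% of the chd1 reads. The domain with the most reads lay on chromosome 3 from 26965001 to 27027000, with 7065 HY reads and 7392 chd1 reads, a log2 ratio of -0.22 (interval -0.27 to -0.17). The next lay on chromosome 11 from 25343001 to 25401000 (5469 and 5530 reads, -0.27) and on chromosome 7 from 2386001 to 2429000 (4670 and 4688 reads, -0.28). Over all domains the median log2 ratio was -0.17 (interval -0.18 to -0.16), with 12 domains at least 2-fold lower in chd1 and 0 higher. Of the 12, 8 lay in 2 stretches of chromosome 11, described with the other observations, and without these stretches 4 were lower. The number also moved with the definition of a domain. It was 13 of 3265 at 3 times the median, 3 of 747 at 6 times, and 5 of 1036 at a shortest length of 5000 bp. TMM moved the median of the domains to 0.00.

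**Figure D2:**
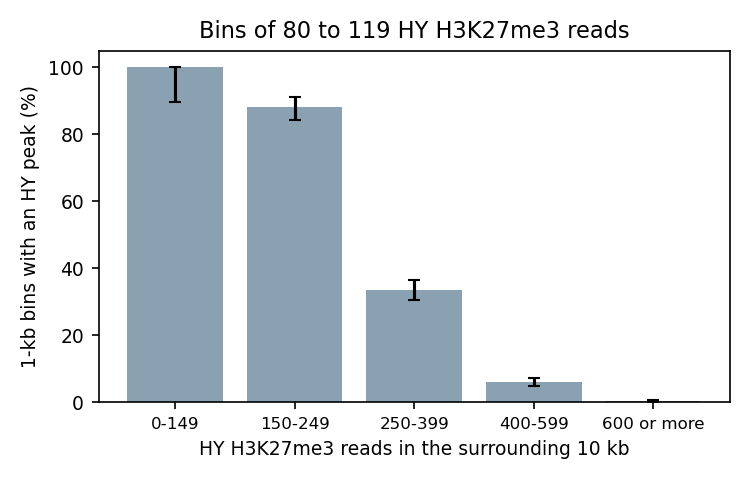
Share of 1-kb bins with at least 80 and fewer than 120 HY H3K27me3 reads that overlapped an HY peak (vertical axis, percent), by the number of HY H3K27me3 reads in the surrounding 10 kb (horizontal axis). Bars are shares with exact 95% binomial intervals that cover counting error only, and they go from 100% at fewer than 150 surrounding reads to 0.366% at 600 or more.

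Families differed in how many of their loci lay in these H3K27me3 domains, and no test of the differences was made. Over all families but retrotransposons the share was 161 of 1238 loci (13.0%, interval 11.2% to 15.01%). It was 7 of 9 loci (77.8%) for the PEBP family, which includes the florigens, 5 of 7 for WOX and 5 of 8 for KNOX homeobox genes, which act in meristems, and 19 of 33 (57.6%) for MADS-box genes, which include floral organ regulators. It was 26 of 62 for NAC, 22 of 80 for WRKY, 20 of 88 for R2R3-MYB and 9 of 63 for AP2/ERF transcription factors, and 18 of 48 for germin-like proteins. It was 2 of 7 for TCP, 2 of 13 for HD-Zip, 1 of 14 for BELL and 0 of 7 for GRAS. Of the receptor kinase loci 6 of 353 (1.70%) lay in a domain, and of the Ty3-gypsy loci 2 of 864 did. The median log2 ratios of the domains of these families were -0.13 for PEBP, -0.17 for WOX, -0.21 for KNOX, -0.20 for MADS-box and -0.22 for NAC, which stood at percentiles 76.1, 59.0, 45.0, 42.1 and 15.3 of random lists. Receptor kinase domains had -0.29 (percentile 7.43) and Ty1-copia domains -0.32 (percentile 2.73), the 2 lowest of the 12 families with at least 5 domains. After the GC adjustment the receptor kinase domains changed side, from -0.12 to 0.034 relative to all domains (percentile 59.7), and the Ty1-copia domains went from -0.15 to -0.13 (percentile 3.78). None of the domains of these 12 families was at least 2-fold different between the libraries.

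In the H3K4me3 regions, 21 families had enough members for a percentile. Light-harvesting chlorophyll proteins had a median log2 ratio of -0.51 over 10 regions, which was -0.16 relative to all regions (percentile 2.43), with 155 HY and 100 chd1 reads on chromosome 8 from 21168351 to 21170070 as an example. Relative to all regions, receptor kinases had -0.060 over 79 regions (percentile 2.25) and BELL homeobox genes -0.19 over 6 (percentile 2.40). After the GC adjustment these percentiles were 8.80, 91.3 and 14.1, and the receptor kinases changed side, at 0.049 relative to all regions. With random lists matched also on which libraries had a peak they were 8.48, 7.92 and 6.58. Only loci with a peak enter these values. Over the windows of all loci the median log2 ratio was -0.28 for 12 light-harvesting loci, 0.017 for 353 receptor kinase loci and -0.094 for 14 BELL loci, and 0.060 for the 8 BELL loci with enough reads within 1500 bp. Ty3-gypsy retrotransposons stood at the other end, with a median of 0.076 over 6 regions (percentile 99.9), and stayed there after the GC adjustment (percentile 99.9). Their median lay 0.43 above that of all regions, and 8 of 864 loci had a chd1 peak against 4 with an HY peak. Of the 6 regions 2 had a peak in chd1 only, which favours higher chd1 reads, and with random lists matched on that the percentile was 97.4. The summed reads of all 864 windows gave a ratio of 0.043. Among them were regions on chromosome 3 from 13360469 to 13361658 (48 and 61 reads, 0.47) and on chromosome 7 from 19476776 to 19478186 (83 and 82 reads, 0.11), while 1 on chromosome 7 from 2501312 to 2503338 had -0.095. No region of these 4 families was at least 2-fold different. The other 17 families stood between percentiles 3.45 for GRAS and 89.1 for ubiquitin, and MADS-box regions stood at 56.3.

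Of 6 families with enough H3K27me3 peak regions, none had a median outside the 95% range of random lists. WRKY regions had a median log2 ratio of -0.40 over 10 regions (percentile 3.29, and 17.4 after the GC adjustment) and R2R3-MYB regions -0.43 over 9 (percentile 6.18, and 5.88 after it). With random lists matched also on which libraries had a peak, these percentiles were 6.62 and 2.55. Cytochrome P450 regions had -0.40 over 22, which was -0.14 relative to all regions and 0.041 after the GC adjustment. Of the 22, 3 were at least 2-fold lower in chd1, such as a region on chromosome 10 from 13587257 to 13588873 (94 and 39 reads, -1.54). In the AP2/ERF family, named for a DNA-binding domain of ethylene response factors, 2 of 7 regions were lower, on chromosome 2 from 33101430 to 33102841 (84 and 29 reads, -1.80) and on chromosome 10 from 11660106 to 11661626 (92 and 36 reads, -1.63). The cytochrome P450 region on chromosome 10 and both AP2/ERF regions were past the rule under TMM, with reads in bins without a peak as the scale and after the GC adjustment. After that adjustment the cytochrome P450 region had -1.02 and the AP2/ERF region on chromosome 10 had -1.10. Both lay close to the threshold of a fold of 2, while the AP2/ERF region on chromosome 2 had -1.64. As above, the scale of bins without a peak hardly moved an H3K27me3 ratio. Receptor kinase and Ty1-copia regions stood at percentiles 45.6 and 32.9.

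The overlap of the marks was compared next, as counts of H3K27me3 peaks that overlapped an H3K4me3 peak. In HY, 340 of 2625 H3K27me3 peaks did (13.0%, interval 11.7% to 14.3%), and in chd1 91 of 1780 did (5.11%, interval 4.14% to 6.24%). Peaks placed at random gave 363.75 and 188.16 on average, so the overlap was below that mean in both genotypes, within the range of 310 to 399 in HY and under the range of 163 to 217 in chd1. The shorter chd1 lists enter these numbers. At a score of at least 100 the shares were 40 of 507 (7.89%, interval 5.70% to 10.6%) in HY and 23 of 297 (7.74%, interval 4.97% to 11.4%) in chd1, and with lists of the chd1 lengths HY had 160 of 1780 (8.99%, interval 7.70% to 10.4%). The H3K27me3 regions lower in chd1 overlapped an HY H3K4me3 peak in 40 of 173 cases (23.1%, interval 17.1% to 30.1%), against 276 of 2747 (10.05%, interval 8.95% to 11.2%) among those neither lower nor higher. With calls made after the GC adjustment the shares were 16 of 69 (23.2%, interval 13.9% to 34.9%) and 300 of 2850 (10.5%, interval 9.42% to 11.7%). Lower H3K27me3 regions had a median GC content of 61.2% against 47.95% in those neither lower nor higher, and 58.7% against 48.5% with calls made after the GC adjustment. Without that adjustment, overlaps with a chd1 H3K4me3 peak were 18 of 173 (10.4%) and 129 of 2747 (4.70%). The groups were not matched on which libraries had an H3K27me3 peak. The rule for lower regions favours those with an HY peak, and this was not separated from the difference in overlap.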

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

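Base differences in the reads and the 1-kb bins without reads were examined only after the mark comparisons had been seen. The comparisons did not use the base differences, while the bins held the same kept reads. Both genotypes differed from the reference at 17687 sites, where at least 3 reads and at least 80% of the reads carried the other base. The chd1 reads differed at 423 sites where at most 20% of the HY reads carried the same differing base. By the same rule the HY reads differed at 113 sites. These lay among 42847434 bases covered by at least 3 reads in both genotypes. They are listed because each is more than the 3 that a count of 0 allows, which says nothing on sequencing error or depth as the source of the sites, and the depths of the genotypes differed, so their sizes were not compared. Of the 1-kb bins with at least 20 reads in HY, 0 of 263285 had no chd1 reads, and 0 of 284172 had no HY reads in the reverse comparison.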

How the results depend on the processing

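The GC adjustment, the removal of the long blocks, the alternatives for peaks of both marks in chd1, the lists of equal length for them and every alternative of the dense domains were chosen after seeing the data, and the others were planned. No paired analysis was possible because each group holds 1 library, and the planned windows around transcription starts were not run for want of an annotation of this build. No result over peak regions or domains rose above 0 in its median except under TMM, which centres the median by construction. In the simulations the rule found 100% of the 3-fold changes. Only regions with a mean of at least 50 reads in 1 of the libraries were changed, and the change then raised the reads of the higher library further. Changed regions near the minimum of 50 reads in the higher library were thus not simulated at that fold, and 100% is not a detection rate for them.

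Under TMM the medians were 0.00 for H3K4me3 (0.00226), -0.00 for H3K27me3 (-0.000463) and 0.00 for the domains (0.000283), with 16 lower and 41 higher H3K4me3 regions and 81 lower and 32 higher H3K27me3 regions. All 16 and all 81 were among the main calls, which had to be so, since TMM raised every ratio of a mark alike. With reads in bins without a peak as the scale, the H3K4me3 median was -0.46 with 374 lower regions, and the domain median was -0.18. With duplicates kept, the medians were -0.37 for H3K4me3 and -0.31 for H3K27me3, with 298 lower and 45 higher H3K4me3 regions and 13 higher H3K27me3 regions. With reads of several places kept, the H3K4me3 median was -0.39 with 37 higher regions. Without the read shift, 12 H3K27me3 regions were higher. After the GC adjustment the medians were -0.28 for H3K4me3, -0.18 for H3K27me3 and -0.23 for the domains, with 109 lower H3K4me3 and 69 lower H3K27me3 regions, of which 90 and 67 were among the main calls.

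With a pseudocount of 5 the H3K4me3 median was -0.32. Over HY peaks only the medians were -0.36 for both H3K4me3 (-0.360) and H3K27me3 (-0.361), and over chd1 peaks only they were -0.31 and -0.092. These lists choose regions by 1 of the libraries compared. By construction, a fold of 1.5 gave more calls, 2798 lower and 51 higher for H3K4me3 and 577 and 65 for H3K27me3, and a fold of 3 gave fewer, 4 and 9 for H3K4me3 and 31 and 1 for H3K27me3. With a minimum of 20 reads, and with none, 55 H3K4me3 and 11 H3K27me3 regions were higher. In 2-kb bins with or without a peak, 147 were lower and 138 higher for H3K4me3, and 450 were lower and 450 higher for H3K27me3.

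HY peaks without a chd1 peak were 44.2% for H3K4me3 and 63.1% for H3K27me3 at a score of at least 100, 13.3% and 46.7% among equally many top peaks, and 24.8% for H3K4me3 when 50% of the peak had to be covered. Peaks of both marks were 40 in HY and 23 in chd1 at a score of at least 100, and 160 in HY with lists as long as those of chd1. The domains at least 2-fold lower were 3 at 6 times the median, 5 at a shortest length of 5000 bp and 4 without the long blocks, and the domain median was -0.13 at 3 times and -0.22 at 6 times the median. The cause of these changes was not tested. Those under TMM, the folds and the lists of 1 library follow at least in part from how these settings are built. Of 196 values of the 28 named regions under alternatives, 4 left their counting interval and 0 changed sign, and of 189 values of the 27 families, 7 left theirs, all after the GC adjustment. The named regions were chosen for large folds, so the scalings could not change their sign. TMM and the scale of bins without a peak shift all regions alike. That shift cancels in a family's value relative to all regions, so those values were the same by construction. Of the 30 values of the long blocks, 10 left their interval and 0 changed sign. The medians stayed in their interval under 3 of 11 alternatives for H3K4me3, 6 for H3K27me3 and 6 for the domains. The numbers of lower regions stayed within 1.5 times under 7 of 13 alternatives for H3K4me3 and 8 for H3K27me3, those of higher regions under 5 for each mark, and that of lower domains under 8 of 11.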

Other observations

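Of the tests below, those on reads of several places and on GC content in chromosome 11 were written before their values were seen, and the tests on the local background, read density, copy number, sequence differences, peaks, extra DNA and evenness were written after. The domains and blocks were themselves chosen after the data were examined.

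In 2 stretches of chromosome 11 H3K27me3 was lower in chd1 over 80 kb and 160 kb. From 17870001 to 17950000 the HY library held 4783 H3K27me3 reads and the chd1 library 2106, a log2 ratio of -1.47 (interval -1.54 to -1.39), and from 18060001 to 18220000 they held 12360 and 6006, a ratio of -1.33 (interval -1.37 to -1.28). The dense domain from 18170001 to 18186000 had 1901 and 383 reads, a ratio of -2.60. The 4 H3K4me3 peak regions in these stretches all had a peak in chd1 only, which favours higher chd1 reads in them, and held 47 and 89 reads in the shorter stretch (1.04) and 46 and 89 in the longer (1.07), against ratios of 0.045 and 0.10 outside them. Of the 4, the region from 18170012 to 18171106 passed the rule, with 24 and 60 H3K4me3 reads (1.43, interval 0.74 to 2.19) and 121 and 20 H3K27me3 reads (-2.85). H3K4me3 was higher in chd1 in 3 other stretches, on chromosome 1 from 33510001 to 33590000 (0.81), on chromosome 9 from 4690001 to 4730000 (1.06) and on chromosome 12 from 20440001 to 20640000 (1.25, interval 1.18 to 1.32). H3K27me3 there had ratios of -0.091, -0.14 and -0.20.

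For the chromosome 11 stretches, a lower copy number in chd1 would lower H3K4me3 too, but its log2 ratio over the whole stretches was 0.13. With reads of several places kept the H3K27me3 ratio was -1.30, and less the median of domains of like GC content it was -1.24. Neither of these accounts for the pattern. Among 81980 bases covered in both genotypes 0 sites differed, which argues only against a stretch rich in base differences. Over all 42847434 such bases 423 and 113 sites differed, so a count near 0 was likely here. It does not exclude a sequence difference. Extra copies of whole stretches in the HY H3K27me3 library would give the 10-kb bins of a stretch 1 ratio, but these went from -2.63 to -0.57 in the longer stretch, and the chi-square over its degrees of freedom was 27.7 over both stretches. The ratio outside dense domains less that inside was 0.016, which leaves DNA added unevenly in 1 library open. A lower H3K27me3 level over these stretches in chd1 stays open as a hypothesis.

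For the H3K4me3 stretches on chromosomes 1, 9 and 12, a copy number gain in all chd1 plants would raise H3K27me3 too, but its ratio was -0.16. A gain at H3K4me3 peaks alone would leave the reads outside peaks as they were, but their ratio was 1.13 (interval 1.07 to 1.19). The stretches were chosen by all their reads, of which most lay outside peaks (3491 HY reads, against 691 inside). That choice favours a high ratio outside peaks, and the interval does not cover it. The ratio thus describes these stretches only. The ratio inside peaks less that outside was -0.073, which decides nothing on extra DNA, since the stretches were chosen by their reads. Extra copies of whole stretches in the chd1 H3K4me3 library are a candidate explanation, since the 10-kb bins of a stretch were even, with a chi-square over its degrees of freedom of 0.760 over the 3 stretches. The choice of the stretches by their reads and the trimming of their ends can favour evenness. Stretches outside the blocks were not measured for reference. A gain of the mark over the whole stretches, or a copy number gain in the plants of that library only, was not tested apart from such extra copies. The labels do not say whether both marks came from the same chromatin.

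Most dense H3K27me3 domains held no peak, and the local background used by the caller is a candidate explanation. Among 1-kb bins of at least 80 and fewer than 120 HY reads, the share with a peak was 100% where the surrounding 10 kb held fewer than 150 reads and 0.366% where they held 600 or more, a difference of 99.6 percentage points, which argues against too few reads as the cause. The read density in domains without a peak was 0.998 times that in domains with one, which met neither bound written for that comparison and decided nothing. Reads of several places were 0.295 times as frequent in the domains without a peak, which argues against repeated copies. No biological explanation was tested, since the pattern is about the calling in HY, and among the densest 0.1% of 1-kb bins 6.99% held an HY peak for H3K27me3 against 97.3% for H3K4me3.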
